A study of Mus musculus with 16 samples.

How the data were processed

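Poly-A RNA of inguinal white adipose tissue from C57BL6/J mice was sequenced in 16 libraries. Per the labels, the mice received a control or a high-fat diet and either no antibody or an antibody against PDGFcc, a platelet-derived growth factor ligand. The antibody (AF1447) was given into the peritoneum every 2 days for 2 weeks from 6 weeks of age, each dose being 50 mg/kg in a volume of 100 µl. RNA was extracted with TRIzol and a lipid tissue kit, and stranded libraries were prepared from the poly-A fraction. Whether the untreated mice received a control injection, how long the diets lasted and at what time of day tissue was collected are not given in the sources used here.

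Per the submitters' processing notes, fastp 0.20.1, STAR 2.7.0e, featureCounts, Subread 1.6.2 and limma 3.42.2 were used with the mouse builds mm10 and GRCm38; the role and order of each tool are not given in the sources used here. The deposited table holds a linear signal per gene and library, which its name calls normalized counts, for 16091 genes in 16 columns. The normalization method and the filter on low genes are not given in the sources used here, nor is whether reads were counted by strand. The values were not whole numbers, and whole reads could not be recovered from their steps, so no count model was run and the read depth before normalization is unknown. Column totals lay between 24.02 and 28.15 in units of 1e6 normalized counts, 255 values were 0, 0 columns were left unmapped and 0 pairs of columns were identical. Of the gene identifiers, 16081 were found in the GENCODE vM21 annotation of GRCm38, 15883 of them with the same symbol, and coordinates come from that annotation. Among the symbols 7 occurred more than once. Of 80 genes named in the text and looked up, 12 share exon sequence with a tested gene on the opposite strand (Mest, Elovl6, Cxadr, Cebpa, Wdr6, Cd180, Xrcc3, Lysmd4, Chaf1a, Nmrk2, Alkal2 and Adamts4) and 1 on the same strand (Mir22hg), and their values are uncertain to that extent.

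The plan had assumed log2 values or CPM. Since the values were linear, the conversion to log2(value + 1) set for that case was used, and a value of 24.49, the median column total divided by 1e6, stood for 1 CPM. Genes above 1 CPM by that measure in at least 4 libraries were tested, which kept 14189 genes and left out 1902. Fold changes on the log2(value + 1) scale understate the change of low genes. Group means and SDs are of normalized counts over 4 libraries.

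A linear model with 1 mean for each of the 4 groups was fitted to all 16 libraries with limma 3.58.1 in R 4.3.3, with variances moderated along a trend with expression (residual degrees of freedom 12, prior degrees of freedom 3.07). The 5 contrasts gave the diet effect without antibody, the antibody effect on each diet, the diet effect with antibody and the interaction of diet and antibody. Tests were two-sided, p-values were adjusted by Benjamini and Hochberg within each contrast, and an adjusted p under 0.05 was the threshold. The labels do not say whether libraries came from separate animals, so p-values measure the spread between these samples, which may be technical in part.

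There were 30 gene lists: adipogenic transcription factors, mature adipocyte, de novo lipogenesis, triglyceride synthesis and lipid droplet, lipolysis, fatty acid oxidation, thermogenic adipocyte, oxidative phosphorylation, cholesterol biosynthesis, PDGF ligands and receptors, adipose progenitor, extracellular matrix, macrophage, lipid-associated macrophage, inflammatory cytokines and chemokines, interferon response, B cell, plasma cell and germinal centre, T cell, neutrophil, endothelial, mural, skeletal muscle, mammary and skin epithelium, Schwann cell and nerve, blood and haemoglobin, proliferation, immediate early and stress, circadian clock, and sex-linked genes. Each was tested against the other genes with camera at a preset correlation of 0.01 between genes, adjusted over 150 tests of lists and contrasts, and again with an estimated correlation. Members past the threshold were counted over all genes and adjusted over the list alone. Differences of a list's mean between 2 groups were also tested by exact two-sided permutation over the 70 assignments of 4 against 4 libraries, for which the smallest possible p is 0.0286.

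For each contrast the text names the 10 largest rises and 10 largest falls past the threshold with a group mean of at least log2 CPM 1 and a symbol that is not a predicted gene, up to 4 members of each list, and in every case Pdgfc, Pdgfra, Pdgfrb, Plat, Pparg, Cebpa, Adipoq, Lep, Ucp1 and Fasn. For the interaction the rule takes 5 each way, and where no gene passes, those with the smallest p. The contrasts, tests, lists, naming rule and the alternative settings so marked below were set before the data were examined.

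The fit was tested on simulated data with 50 changed genes per fold size among 14189. For the diet effect without antibody it recovered 56%, 88%, 98% and 100% of genes changed by log2 0.5, 1, 2 and 4, with 2.84% of its calls false. For the antibody effect on the high-fat diet it recovered 40%, 80%, 98% and 100%, with 5.36% false. The simulated noise was drawn independently for each gene, with the same SD in every library. In the real libraries genes moved together and the spread differed between libraries, so these shares may not hold there.

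Alternative settings written before the data were seen were no filter, a stricter filter (log2 CPM above 1 in at least 8 libraries), quantile normalization, centring on the library median, pseudocounts of 0.5 and 4, no variance trend, weights per library, only the groups compared, the replicate number as a block, also within each diet, a log2 fold change of at least 1, and leaving out each library in turn. Chosen after seeing the data were leaving out 2 doubted libraries together (untreated control-diet replicate 3, with the largest total and the highest Ucp1, and untreated high-fat replicate 2, with the highest level of skeletal muscle genes), a skeletal muscle score as a covariate and a circadian clock score as a covariate. The muscle score is the mean log2 value of the 14 muscle genes, and the clock score is the mean of 9 clock genes (Dbp, Tef, Hlf, Per3, Ciart, Bhlhe41, Nr1d2, Per2 and Cry2) minus that of 3 in antiphase (Arntl, Npas2 and Clock). These 12 genes were chosen after the data were seen and leave out Per1, Cry1 and Nr1d1 of the clock list. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.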

Results

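Messenger RNA was measured in inguinal white adipose tissue, the subcutaneous fat pad of the groin, in 4 groups of 4 libraries: control diet untreated, control diet with anti-PDGFcc antibody, high-fat diet untreated and high-fat diet with antibody. PDGF-CC is a ligand of the receptor PDGFRA, which marks adipocyte progenitors, and the series title asks about adipogenesis pathways under the antibody. In the table of normalized counts 14189 genes were tested and 1902 were left out as low. Library totals, in units of 1e6 normalized counts, lay between 24.02 (untreated high-fat replicate 4) and 28.15 (untreated control-diet replicate 3). Scd1, the main fatty acid desaturase of fat, was the most abundant gene in every library, with 3.07% to 9.1% of the total. Across genes, log2 values of libraries within a group correlated at r = 0.9542 to 0.9819 (control diet untreated), 0.9836 to 0.992 (control diet with antibody), 0.9499 to 0.9905 (high-fat untreated) and 0.9788 to 0.9879 (high-fat with antibody). Genes are not independent replicates. The first and second principal components held 39.1% and 24.8% of the variance.

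The first comparison asked what the high-fat diet changed in mice without antibody. Most genes that build fatty acids fell on the high-fat diet: of 21 measured de novo lipogenesis genes, 13 fell, 0 rose and 8 did not pass, and adjusted over the list alone 20 fell. Fasn, the fatty acid synthase (ENSMUSG00000025153, GRCm38 chromosome 11, 120805846 to 120824547), went from 584900 ± 257300 to 114300 ± 57250 normalized counts (SD, n = 4), a log2 change of -2.35 ± 0.40 (SE; adjusted p = 0.0136, limma). Acly, which makes cytosolic acetyl-CoA (ENSMUSG00000020917, chromosome 11, 100476353 to 100528000), went from 82340 ± 47690 to 11560 ± 3634, by -2.64 ± 0.44 (adjusted p = 0.0136). Slc2a5, the fructose transporter (ENSMUSG00000028976, chromosome 4, 150119283 to 150144169), went from 821.1 ± 544.1 to 44.04 ± 56.02, by -4.76 ± 0.88 (adjusted p = 0.0149), and the fatty acid elongase Elovl6 by -3.54 ± 0.64 (adjusted p = 0.0149). For these 4 genes all 4 high-fat libraries lay below all 4 control-diet libraries. Acss2, Me1 and Fads2, which supply acetyl-CoA and NADPH or desaturate fatty acids, changed by -2.10 ± 0.32, -1.98 ± 0.33 and -0.96 ± 0.14 (adjusted p = 0.0136 each). The list had a median log2 change of -1.13 (camera adjusted p = 5.18e-15 with the preset correlation, adjusted p = 0.718 with an estimated correlation). The exact permutation p of its mean was 0.0286, the smallest the design allows (0.214 after adjustment). The median stayed between -1.44 and -1.03 with each library left out in turn. The calls of Fasn, Acly and Elovl6 ended without untreated control-diet replicate 4 (0 genes past the threshold) and without untreated high-fat replicate 4 (0 genes), with adjusted p up to 0.0548 for Fasn and Acly and 0.0706 for Elovl6. Slc2a5 lost its call without the same libraries (0.0706 and 0.0548) and without untreated control-diet replicate 3 (0.0508). With only the groups compared 0 genes passed, so all these calls rest on a spread estimated in part from the antibody libraries. The SD of the lipogenic list mean was 0.612 and 0.283 in untreated control-diet and high-fat libraries. It was 0.299 and 0.116 in the antibody libraries of these diets.

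**Figure D1:**
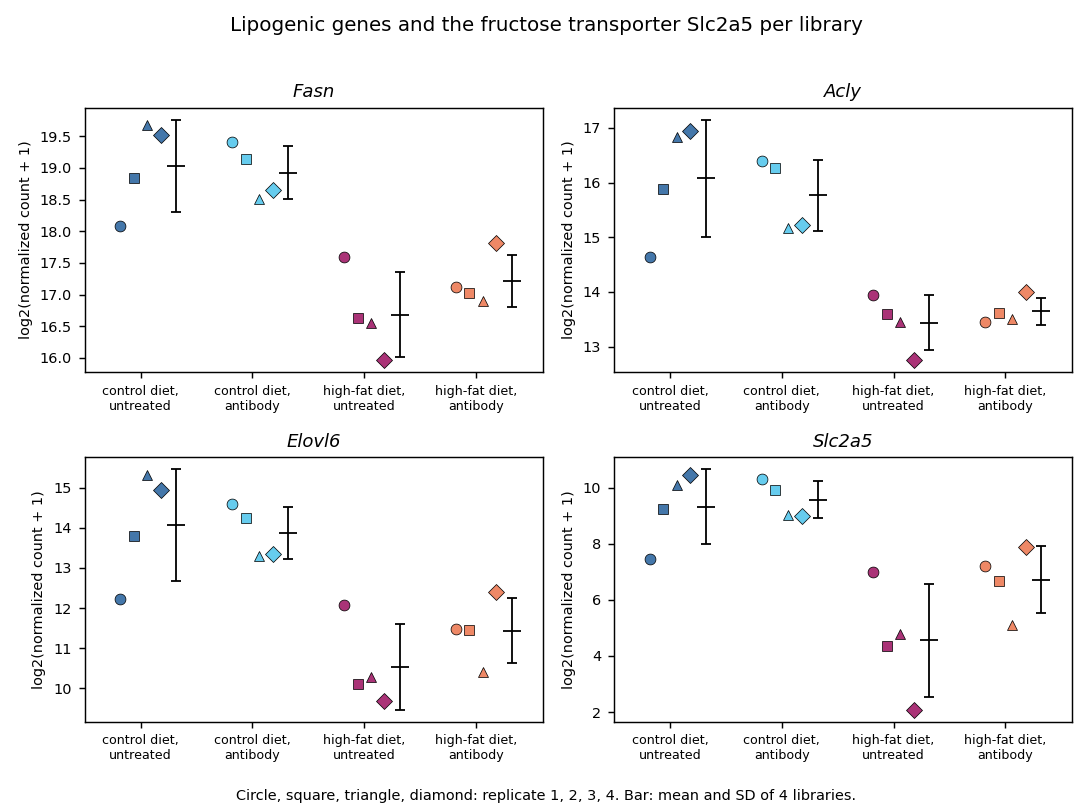
Log2(normalized count + 1) of Fasn, Acly, Elovl6 and Slc2a5 in each library, by group, with a marker for each replicate number and a bar at the mean ± SD of 4 libraries. All 4 untreated high-fat libraries lie below all 4 untreated control-diet libraries, and Fasn differed by -2.35 on the log2 scale.

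Most oxidative phosphorylation genes and a minority of cholesterol biosynthesis genes fell on the same diet. All 27 measured genes of oxidative phosphorylation were lower, 19 past the threshold and 8 not, and adjusted over the list alone 27 fell. The list median was -0.79 (adjusted p = 8.05e-14, adjusted p = 0.871 with an estimated correlation, exact permutation p = 0.0571). Examples are the complex subunits Sdhc (-0.62 ± 0.15, adjusted p = 0.0342), Ndufv2 (-0.77 ± 0.20, 0.0372) and Cox5a (-1.03, 0.0382). Of 19 cholesterol biosynthesis genes 7 fell and 12 did not pass, 11 adjusted over the list alone (median -0.78, adjusted p = 1.2e-06, adjusted p = 0.871 with an estimated correlation). They were led by the farnesyl diphosphate synthase Fdps (-1.23 ± 0.20, adjusted p = 0.0136) and the sterol dehydrogenase Nsdhl (-1.12 ± 0.19, 0.0136). Among 20 fatty acid oxidation genes 0 passed over all genes by limma and 11 were lower adjusted over the list alone (median -0.78; adjusted p = 5.82e-05, adjusted p = 0.88 with an estimated correlation). The thioesterase Acot2 was at -0.93 ± 0.28 (adjusted p = 0.051). Of 18 thermogenic adipocyte genes 1 fell, the potassium channel gene Kcnk3 (-1.20 ± 0.34, adjusted p = 0.046), and 6 adjusted over the list alone (median -1.72; adjusted p = 0.000126, adjusted p = 0.88 with an estimated correlation). Ucp1, the uncoupling protein of brown and beige fat, was at -5.10 ± 1.96 (adjusted p = 0.101). It had 16100 ± 20030 normalized counts on the control diet and 1564 ± 2993 on the high-fat diet, so its spread exceeded its mean in both groups. Of 19 triglyceride synthesis and lipid droplet genes 4 fell, among them Agpat2 (-1.25 ± 0.31, adjusted p = 0.0362) and Dgat2 (-0.68 ± 0.18, 0.0413). Adjusted over the list alone 8 fell and 1 rose (median -0.28, adjusted p = 0.0162, adjusted p = 0.88 with an estimated correlation). Of 14 lipolysis genes 1 fell over all genes and 1 adjusted over the list alone, the protein kinase A subunit Prkaca (-0.65 ± 0.11, adjusted p = 0.0136). The list median was -0.21 (adjusted p = 0.0365, adjusted p = 0.88 with an estimated correlation). The triglyceride list lost its call without untreated control-diet replicate 3 (adjusted p = 0.184), without untreated high-fat replicate 2 (0.0525), without both of them (0.434) and with quantile normalization (0.0554). The lipolysis list lost it without untreated control-diet replicates 2 and 3 (0.0614 and 0.186), without untreated high-fat replicates 2 and 3 (0.162 and 0.0846) and without both doubted libraries (0.582). It also lost it with quantile normalization (0.202) and with the muscle score as a covariate (0.0817). Untreated replicate 1 of each diet ran against most of these falls, by list means as deviations from all libraries. On the control and high-fat diets these were -0.2877 and -0.06297 for oxidative phosphorylation, -0.6585 and 0.2155 for fatty acid oxidation and -1.649 and 0.7246 for thermogenic genes. For triglyceride genes they were -0.2453 and 0.1544, and for lipolysis -0.1542 and 0.1092. Cholesterol genes ran with the fall (-0.2232 and -0.3557).

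A minority of the genes of matrix, dividing cells, macrophages and immediate early response rose on the high-fat diet without antibody. All 27 extracellular matrix genes were higher, 5 past the threshold and 22 not, 13 adjusted over the list alone (median 0.53, adjusted p = 8.18e-08, adjusted p = 0.871 with an estimated correlation). Among them were the collagen crosslinker Lox (0.65 ± 0.14, adjusted p = 0.0273) and the collagen VI chain Col6a3 (0.84 ± 0.20, 0.031). Of 18 proliferation genes 7 rose, 14 adjusted over the list alone (median 0.65, adjusted p = 7.88e-07, adjusted p = 0.871 with an estimated correlation). Examples are Mki67 (0.78 ± 0.18, adjusted p = 0.0304) and the cyclin Ccna2 (0.81 ± 0.22, 0.041). Of 20 macrophage genes 2 rose, among them Cd68 (0.76 ± 0.20, adjusted p = 0.04), and 6 adjusted over the list alone (median 0.51, adjusted p = 5.49e-05, adjusted p = 0.88 with an estimated correlation). Untreated replicate 1 of each diet ran against that rise. Its macrophage list mean, as a deviation from all libraries, was 0.3576 on the control diet and -0.2285 on the high-fat diet. Of 14 immediate early and stress genes 3 rose and 8 adjusted over the list alone (median 0.74; adjusted p = 0.000341, adjusted p = 0.871 with an estimated correlation). These were Fos (1.91 ± 0.35, adjusted p = 0.0149), Zfp36 (0.56 ± 0.14, 0.034) and Nr4a1 (1.71 ± 0.42, 0.0342). Of 13 inflammatory cytokines and chemokines Ccl7, a monocyte attractant, rose (2.02 ± 0.48, adjusted p = 0.031), and 3 adjusted over the list alone (median 0.61; adjusted p = 0.00439, adjusted p = 0.871 with an estimated correlation). All 20 adipose progenitor genes were higher, 1 of them past the threshold over all genes and adjusted over the list alone, Icam1 (0.55 ± 0.13, adjusted p = 0.03). The list median was 0.34 (adjusted p = 0.00373, adjusted p = 0.88 with an estimated correlation, and 0.0508 without untreated control-diet replicate 3). Untreated replicate 1 ran against this rise too, with a progenitor list mean of 0.3224 on the control diet and -0.06755 on the high-fat diet. So it did for matrix (0.186 and 0.1495) and inflammatory genes (0.03431 and -0.04536). It ran with the rise of proliferation (-0.144 and 0.3997) and immediate early genes (-0.3819 and -0.08644). In the list of lipid-associated macrophages Cd9 rose (0.58 ± 0.14) while Fabp5 (-0.97 ± 0.24) and Ctsd (-0.56 ± 0.14) fell. Of its 15 genes 5 rose and 3 fell adjusted over the list alone, and the list did not pass (adjusted p = 0.171).

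Adipocyte identity genes did not pass as a group with the diet. Of 24 mature adipocyte genes 2 rose, Nnat (1.13 ± 0.29, adjusted p = 0.0379) and Sncg (1.003 ± 0.28, 0.0426), and the glucose transporter Slc2a4 fell (-0.77 ± 0.16, 0.0242). Adjusted over the list alone 3 rose and 1 fell. The list median was -0.03, its mean 0.01 and its test pointed down (adjusted p = 0.867). The adiponectin gene Adipoq was at 0.03 ± 0.11 (adjusted p = 0.883) and the leptin gene Lep at 0.82 ± 0.37 (0.15). Of 18 adipogenic transcription factors 0 passed by limma, over all genes or adjusted over the list alone (median 0.04, mean -0.005; adjusted p = 0.896). Of these, Pparg and Cebpa were at -0.53 ± 0.25 (adjusted p = 0.167) and -0.15 ± 0.13 (0.426). None of 9 genes of PDGF ligands and receptors passed, with 8 of them higher (median 0.28, adjusted p = 0.0638). Pdgfc was at 0.28 ± 0.18 (adjusted p = 0.305), Pdgfra at 0.42 ± 0.16 (0.0964), Pdgfrb at 0.35 ± 0.14 (0.11) and Plat, the protease that activates PDGF-CC, at 0.50 ± 0.24 (0.18). The endothelial gene Egfl7 (0.38 ± 0.11, adjusted p = 0.0444) and the mural gene Tagln (0.53 ± 0.14, 0.0371) rose, with lists at adjusted p = 0.187 and 0.194. No other list passed, with adjusted p = 0.0533 for interferon response (16 genes), 0.0983 for Schwann cell and nerve (9), 0.261 for circadian clock (15), and 0.3 for neutrophil genes (5). It was 0.835 for sex-linked genes (4), 0.851 for blood and haemoglobin (5), 0.864 for plasma cell and germinal centre (7), 0.915 for B cell (3), 0.915 for T cell (10) and 0.98 for mammary and skin epithelium (4). The 14 skeletal muscle genes, markers of a neighbouring tissue, had a median of 2.25 with 0 genes past the threshold (adjusted p = 0.211; exact permutation p of the mean 0.486).

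In all, 1157 genes passed the threshold between the diets without antibody by limma, 423 higher and 734 lower on the high-fat diet, 172 of them at least 2-fold. By size, the list of rises was led by Sez6l (3.19 ± 0.80, adjusted p = 0.0362), the pentraxin Ptx3 (2.51 ± 0.61, 0.0338), the metallothionein Mt2 (2.27 ± 0.59, 0.039) and Cthrc1 (2.03 ± 0.58, 0.0455). Mest, a gene tied to fat expansion, rose by 1.97 ± 0.56 (0.0455), from 1778 ± 1226 to 6513 ± 2924 normalized counts (n = 4). Tph2, Bpifb6 and Arc rose by 1.95, 1.91 and 1.84. Besides the lipogenic genes, the largest falls were in Ttc25 (-2.80 ± 0.69, adjusted p = 0.0342), Sorcs2 (-2.78 ± 0.71, 0.0371), the glycogen-targeting subunit Ppp1r3b (-2.70 ± 0.72, 0.0408) and Cxadr (-2.69 ± 0.77, 0.046). They were followed by Slc25a48 (-2.66 ± 0.66, 0.0357), the nuclear receptor Esrrg (-2.46 ± 0.57, 0.0299) and Hephl1 (-2.37 ± 0.58, 0.0342). Without untreated control-diet replicates 1 to 4 the count was 4119, 338, 93 and 0, and without untreated high-fat replicates 1 to 4 it was 1953, 117, 82 and 0. Leaving out antibody libraries, which share only the estimate of spread, gave 561 and 579 without control-diet replicates 2 and 3 and 577 and 617 without high-fat replicates 2 and 4. Without both doubted libraries (untreated control-diet replicate 3 and untreated high-fat replicate 2), or with only the groups compared, it was 0, and with the muscle score as a covariate 119.

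The next comparison asked what the antibody changed on the high-fat diet, where 11 genes passed the threshold, 5 higher and 6 lower, 7 of them at least 2-fold. Zbtb16, a zinc finger transcription factor (ENSMUSG00000066687, chromosome 9, 48654297 to 48836222), fell from 4360 ± 1572 to 892.8 ± 193.8 normalized counts (n = 4), by -2.24 ± 0.27 (adjusted p = 0.00623). Cdkn1a, an inhibitor of the cell cycle (ENSMUSG00000023067, chromosome 17, 29090976 to 29100727), fell from 1340 ± 307.8 to 474.5 ± 182.4, by -1.54 ± 0.25 (adjusted p = 0.0352). The potassium channel gene Kcna1 (-1.46 ± 0.24, 0.0352) and the tubulin-binding Tppp3 (-1.21 ± 0.20, 0.0375) fell as well. The arachidonate lipoxygenase Alox12 rose (1.37 ± 0.23, adjusted p = 0.0375), as did Mecom (0.89 ± 0.14, 0.0352) and Wdr6 (0.72 ± 0.12, 0.0352). The chromatin protein gene Bahcc1 (ENSMUSG00000039741, chromosome 11, 120232947 to 120292296) rose from 1193 ± 93.2 to 2378 ± 161.7, by 0.995 ± 0.15 (adjusted p = 0.0344). For each of these 8 genes all 4 antibody libraries lay beyond all 4 untreated ones. Zbtb16 passed with each of the 16 libraries left out, at adjusted p up to 0.0416; the others passed in 4 (Alox12) to 8 (Cdkn1a and Kcna1) of the 16.

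**Figure D2:**
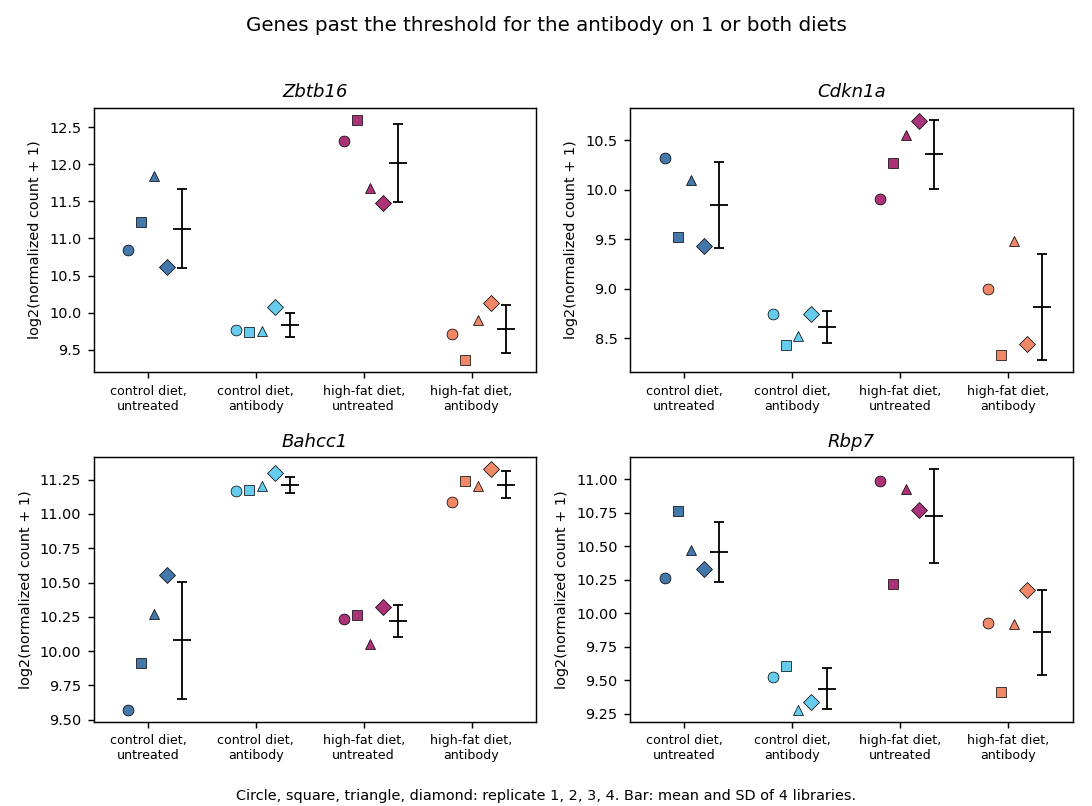
Log2(normalized count + 1) of Zbtb16, Cdkn1a, Bahcc1 and Rbp7 in each library, by group, with a marker for each replicate number and a bar at the mean ± SD of 4 libraries. On the high-fat diet Zbtb16 was lower in all 4 antibody libraries (-2.24 on the log2 scale), and Bahcc1 was higher in all 4 antibody libraries on each diet.

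No gene of the adipogenic or mature adipocyte lists was among those calls, though these lists do not hold every gene with a role in adipogenesis. Of 18 adipogenic transcription factors 0 passed over all genes by limma, and adjusted over the list alone 4 were higher and 1 lower. Zfp467 was at 0.89 ± 0.19 (adjusted p = 0.0769 over all genes), the lipogenic regulator Srebf1 at 0.91 ± 0.26 (0.149) and Klf15 at -0.58 ± 0.14 (0.0905). The list did not pass (median 0.08, adjusted p = 0.146). Pparg was at 0.46 ± 0.25 (adjusted p = 0.449), Cebpa at 0.32 ± 0.13 (0.275), Adipoq at 0.04 ± 0.11 (0.916), Lep at 0.46 ± 0.37 (0.64) and Fasn at 0.53 ± 0.40 (0.607). Among 24 mature adipocyte genes 0 passed by limma, with Trarg1 at 0.61 ± 0.20 (adjusted p = 0.188; list median 0.10, adjusted p = 0.0689). The antibody target Pdgfc was at -0.12 ± 0.18 (adjusted p = 0.828), Pdgfra at -0.25 ± 0.16 (0.535), Pdgfrb at 0.05 ± 0.14 (0.93) and Plat at -0.27 ± 0.24 (0.683). The list of PDGF ligands and receptors had a median of 0.02, a mean of -0.04 and adjusted p = 0.938.

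Several lists moved with the antibody on the high-fat diet by camera with the preset correlation, with 0 of their members past the threshold over all genes by limma. Cholesterol biosynthesis genes were higher in 18 of 19 (median 0.40; adjusted p = 9.38e-05, adjusted p = 0.871 with an estimated correlation). Adjusted over the list alone 3 of them passed, Fdft1 (0.81 ± 0.17), Sc5d (0.84 ± 0.23) and Stard4 (0.63 ± 0.18). De novo lipogenesis genes were higher in 20 of 21 (median 0.21, adjusted p = 0.0133, adjusted p = 0.88 with an estimated correlation). Fatty acid oxidation genes were higher in 19 of 20 (median 0.29, adjusted p = 0.0189, adjusted p = 0.88 with an estimated correlation). Thermogenic genes were higher in 17 of 18 (median 0.65, adjusted p = 0.0287, adjusted p = 0.88 with an estimated correlation). In these 3 lists 0 members passed adjusted over the list alone. Immediate early and stress genes were lower in 13 of 14 (median -0.67; adjusted p = 5.32e-06, adjusted p = 0.871 with an estimated correlation). Of these 6 passed adjusted over the list alone, with Nr4a1 at -1.60 ± 0.42 and Fos at -0.98 ± 0.35. Schwann cell genes were lower in 9 of 9 (median -0.53; adjusted p = 0.00112, adjusted p = 0.871 with an estimated correlation). Of these 2 passed adjusted over the list alone, among them Cdh19 (-0.53 ± 0.18). Macrophage genes were lower in 19 of 20 (median -0.26; adjusted p = 0.00194, adjusted p = 0.88 with an estimated correlation). Interferon response genes were lower in 13 of 16 (median -0.22, adjusted p = 0.0324, adjusted p = 0.88 with an estimated correlation), and 0 of either list passed adjusted over the list alone. With all of these moved the 14 skeletal muscle genes, all lower with the antibody (median -5.32; adjusted p = 4.8e-09, adjusted p = 0.871 with an estimated correlation; 10 adjusted over the list alone). Atp2a1, the calcium pump of fast fibres, was at -7.39 ± 2.11 (adjusted p = 0.155), and the exact permutation p of the muscle mean was 0.0571.

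Without untreated control-diet replicates 1 to 3 the antibody count on the high-fat diet was 70, 1 and 51, without antibody control-diet replicates 2 and 3 it was 1 and 2. Without untreated high-fat replicates 1 to 4 it was 271, 6, 1 and 1, and without antibody high-fat replicates 2 to 4 it was 1, 4 and 3. With the muscle score as a covariate 0 genes passed by limma, and with the clock score 2 passed, 1 of them among the 11. Without both doubted libraries it was 10, with 6 of the 11. List calls ended without untreated high-fat replicate 1 for interferon response (adjusted p = 0.0592), without replicate 2 for fatty acid oxidation (0.151) and thermogenic genes (0.183), and without replicate 3 for macrophage (0.0841) and interferon response (0.141). Without replicate 4 they ended for lipogenesis (0.079), fatty acid oxidation (0.063), thermogenic genes (0.149) and interferon response (0.237). They also ended without antibody high-fat replicate 1 for fatty acid oxidation (0.084) and thermogenic genes (0.219), without replicate 3 for interferon response (0.215) and without replicate 4 for fatty acid oxidation (0.155), thermogenic genes (0.185) and interferon response (0.106). With the muscle score as a covariate the lists of lipogenesis (adjusted p = 0.875), fatty acid oxidation (0.783), thermogenic genes (0.858), cholesterol biosynthesis (0.329) and macrophage (0.105) no longer passed. With the clock score those of cholesterol biosynthesis (0.809), interferon response (0.578) and Schwann cell genes (0.497) did not, and without both doubted libraries those of fatty acid oxidation (0.102) and thermogenic genes (0.198). The thermogenic call also ended after centring on the library median (0.0546). In the fit with the clock score the list means of lipogenesis (-0.232, adjusted p = 0.0518), fatty acid oxidation (-0.391, 0.0308), thermogenic (-0.795, 0.08), macrophage (0.225, 0.00489) and interferon genes (0.0337) had the opposite sign. So did that of thermogenic genes with the muscle score (-0.223).

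On the control diet the same question gave 14 genes past the threshold with the antibody, 8 higher and 6 lower, 5 of them at least 2-fold. Per3, a period gene of the circadian clock (ENSMUSG00000028957, chromosome 4, 151003652 to 151044665), rose from 1359 ± 292.6 to 3325 ± 501.3 normalized counts (n = 4), by 1.30 ± 0.17 (adjusted p = 0.0125). Bahcc1 rose from 1116 ± 324.6 to 2370 ± 97.37, by 1.13 ± 0.15 (adjusted p = 0.0125), and was the only gene past the threshold on both diets. Lzts1 (1.29 ± 0.23, adjusted p = 0.0454), the Toll-like receptor homologue Cd180 (0.89 ± 0.16, 0.0454), Spaca6 (0.85 ± 0.13, 0.0326), Cxxc5 (0.74 ± 0.13, 0.0454), Mir22hg (0.70 ± 0.11, 0.0326) and the Integrator gene Ints6l (0.68 ± 0.10, 0.0186) rose. The recombination gene Xrcc3 (-1.08 ± 0.19, adjusted p = 0.0454), the retinol-binding Rbp7 (-1.02 ± 0.18, 0.0454; 1416 ± 228.9 to 695 ± 74.87 normalized counts) and Banp (-0.92 ± 0.15, 0.038) fell. Ccdc117, Zfr and Crkl fell by 0.46, 0.38 and 0.31. In each of these 14 genes all 4 antibody libraries lay beyond all 4 untreated ones.

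Per3 was the only clock gene past the threshold with the antibody on the control diet. Of 15 circadian clock genes 1 passed over all genes, and adjusted over the list alone 10 were higher and 3 lower. The list median was 0.58 (adjusted p = 4.45e-05, adjusted p = 0.718 with an estimated correlation), and the exact permutation p of the mean was 0.0286 (0.214 after adjustment). Tef was at 0.999 ± 0.19 (adjusted p = 0.0632), Cry2 at 0.48 ± 0.10 (0.0836) and Clock, which is high at the opposite phase, at -0.54 ± 0.11 (0.0729). On the high-fat diet 4 clock genes were higher and 4 lower adjusted over the list alone, with Per3 at 0.84 ± 0.17 (adjusted p = 0.0661) and Arntl at -1.36 ± 0.40 (0.16). The list did not pass (median 0.23, adjusted p = 0.15). Mural genes were higher on the control diet in 8 of 10, 2 adjusted over the list alone, Cspg4 (0.66 ± 0.18) and Kcnj8 (0.59 ± 0.17). The list median was 0.13 (adjusted p = 0.034, adjusted p = 0.88 with an estimated correlation). The mural call ended without untreated control-diet replicates 1, 3 and 4 (adjusted p = 0.0505, 0.131 and 0.106), without antibody control-diet replicate 1 (0.106), without both doubted libraries (0.0674), and with the muscle score (0.372) or the clock score (0.368) as a covariate. With them, 13 of 14 skeletal muscle genes were higher with the antibody on this diet, the opposite direction to the high-fat diet (median 3.82, adjusted p = 1.6e-05, adjusted p = 0.871 with an estimated correlation). Adjusted over the list alone 0 passed, and the exact permutation p of the mean was 0.0286. The mean difference was 3.29, and 1.71 without untreated control-diet replicate 4.

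**Figure D3:**
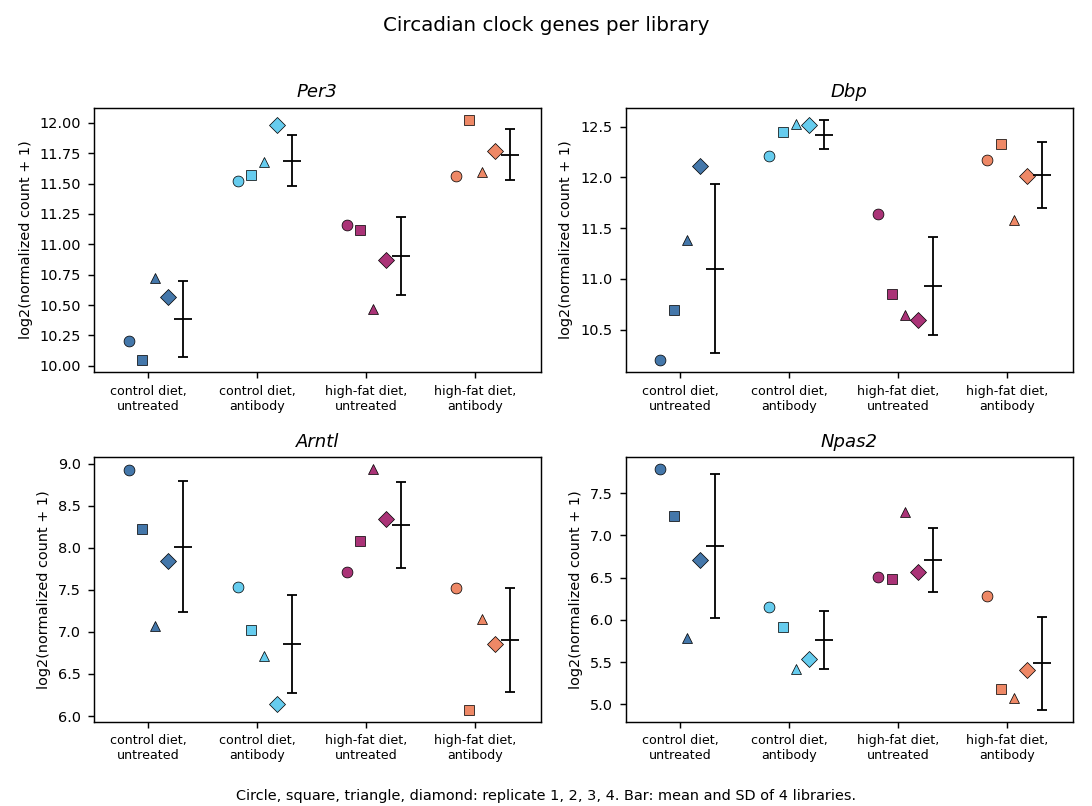
Log2(normalized count + 1) of the clock genes Per3, Dbp, Arntl and Npas2 in each library, by group, with a marker for each replicate number and a bar at the mean ± SD of 4 libraries. Per3 was higher in all 4 antibody libraries on the control diet (1.30 on the log2 scale), and Arntl lay at -1.16 there and at -1.36 on the high-fat diet, not past the threshold.

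Genes of the adipogenic list were again not past the threshold on the control diet. Of 18 adipogenic transcription factors 0 passed over all genes by limma and 1 was higher and 1 lower adjusted over the list alone. Zfp467 was at 0.76 ± 0.19 (adjusted p = 0.137), Klf15 at -0.53 ± 0.14 (0.139), Pparg at 0.02 ± 0.25 (0.988) and Cebpa at 0.20 ± 0.13 (0.592), with the list at adjusted p = 0.147. Mature adipocyte genes had a median of -0.03, a mean of 0.03 and a test that pointed down (adjusted p = 0.736), with 1 lower adjusted over the list alone, Acvr1c (-0.53 ± 0.14). Adipoq was at -0.03 ± 0.11 (adjusted p = 0.956), Lep at 0.88 ± 0.37 (0.365), Fasn at -0.11 ± 0.40 (0.953) and Ucp1 at 0.32 ± 1.96 (0.975). Pdgfc was at 0.02 ± 0.18 (adjusted p = 0.986), Pdgfra at 0.04 ± 0.16 (0.959), Pdgfrb at 0.23 ± 0.14 (0.565) and Plat at 0.05 ± 0.24 (0.968). The count of 14 was 1 and 32 without untreated control-diet replicates 2 and 4, and 3, 3, 0 and 0 without antibody control-diet replicates 1 to 4. It was 22, 86, 6 and 7 without untreated high-fat replicates 1 to 4 and 5, 7 and 3 without antibody high-fat replicates 1 to 3. It was 7 after centring, 5 with the muscle score (3 of the 14) and 0 with the clock score as a covariate, and 21 without both doubted libraries (11 of the 14).

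Between the diets in antibody-treated mice 1 gene passed, Orm3 (ENSMUSG00000028359, chromosome 4, 63356162 to 63359511), of the orosomucoid family of plasma proteins. It fell from 255.1 ± 37.75 to 82.08 ± 4.244 normalized counts (n = 4), by -1.61 ± 0.21 (adjusted p = 0.0254), in all 4 high-fat libraries below all 4 control-diet ones. Its reads may be shared with the near-identical Orm1 and Orm2, so the value is uncertain. At an unadjusted p under 0.05 there were 2574 genes, with 709 given by chance. By camera with the preset correlation the de novo lipogenesis list was lower here too (median -0.80; adjusted p = 2.29e-12, adjusted p = 0.718 with an estimated correlation; exact permutation p 0.0286). Of 21 members 0 passed over all genes and 12 were lower adjusted over the list alone, such as Fasn (-1.71 ± 0.40, adjusted p = 0.0859), Acly (-2.12 ± 0.44, 0.0859) and Acss2 (-1.49 ± 0.32, 0.0859). Oxidative phosphorylation genes were lower in 27 of 27 (0 adjusted over the list alone, median -0.53, adjusted p = 1.88e-11, adjusted p = 0.871 with an estimated correlation). Thermogenic genes were lower in 17 of 18 (0 adjusted over the list alone, median -1.28, adjusted p = 0.00172, adjusted p = 0.88 with an estimated correlation). Cholesterol biosynthesis genes were lower in 16 of 19 (2 adjusted over the list alone, median -0.36, adjusted p = 0.00883, adjusted p = 0.88 with an estimated correlation). Proliferation genes were higher in 18 of 18 (4 adjusted over the list alone, median 0.44, adjusted p = 1.2e-06, adjusted p = 0.871 with an estimated correlation). Extracellular matrix genes were higher in 26 of 27 (1 adjusted over the list alone, median 0.40, adjusted p = 6.03e-06, adjusted p = 0.871 with an estimated correlation). Endothelial genes were higher in 12 of 12 (5 adjusted over the list alone, among them Vwf at 0.75 ± 0.17, median 0.31, adjusted p = 0.000272, adjusted p = 0.871 with an estimated correlation). All 9 genes of PDGF ligands and receptors were higher (1 adjusted over the list alone, Nrp1 at 0.30 ± 0.09, median 0.17, adjusted p = 0.0365, adjusted p = 0.871 with an estimated correlation). Pdgfc was at 0.14 ± 0.18 (adjusted p = 0.721), Pdgfra at 0.13 ± 0.16 (0.699), Pparg at -0.09 ± 0.25 (0.887), Adipoq at 0.10 ± 0.11 (0.667) and Ucp1 at -2.58 ± 1.96 (0.506). Alongside, all 14 skeletal muscle genes were lower (median -6.86; adjusted p = 9.52e-13, adjusted p = 0.718 with an estimated correlation; 13 adjusted over the list alone).

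The count between the diets with antibody was 224 and 100 without untreated control-diet replicates 1 and 4, 0, 0, 0 and 3 without antibody control-diet replicates 1 to 4, and 0 and 239 without untreated high-fat replicates 1 and 2. It was 0 without any 1 of the 4 antibody high-fat libraries, 298 without both doubted libraries and 641 with only the groups compared. In that last setting the diet count without antibody was 0. The main counts of 1157 and 1 therefore do not show that the antibody removed a diet effect. With the muscle score as a covariate Orm3 lost its call (adjusted p = 0.0894) and 1 other gene passed. List calls ended for thermogenic genes without antibody high-fat replicate 3 (adjusted p = 0.0694), for cholesterol biosynthesis without antibody high-fat replicates 1 and 4 (0.0622 and 0.151), and for proliferation with the muscle score (0.152). That of PDGF ligands and receptors ended without antibody control-diet replicate 3 (0.0577), antibody high-fat replicates 3 and 4 (0.0621 and 0.0781), with quantile normalization (0.0721) and with the muscle score as a covariate (0.0614), and without both doubted libraries (0.0522).

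**Figure D4:**
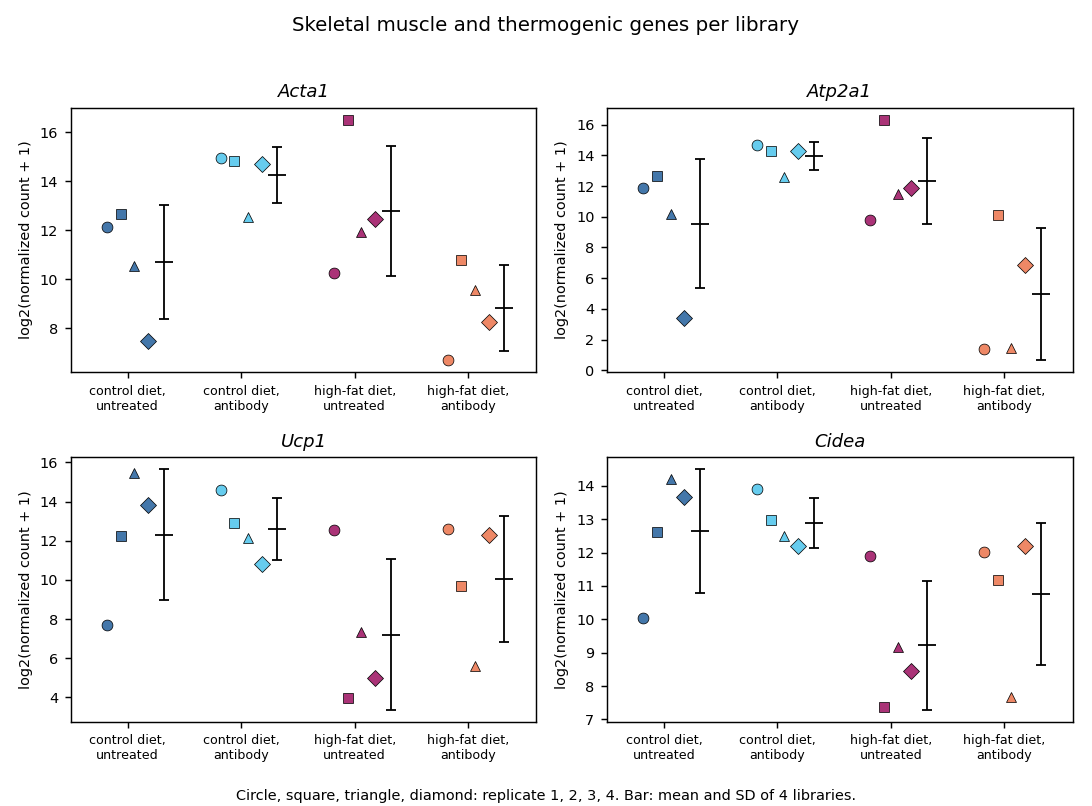
Log2(normalized count + 1) of the muscle genes Acta1 and Atp2a1 and the thermogenic genes Ucp1 and Cidea in each library, by group, with a marker for each replicate number and a bar at the mean ± SD of 4 libraries. Muscle genes were higher with the antibody on the control diet (list median 3.82) and lower on the high-fat diet (-5.32), and Ucp1 in untreated control-diet libraries ranged from 207 to 44771 normalized counts.

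Whether the antibody acted differently on the diets was tested by the interaction, in which 0 genes passed by limma (smallest adjusted p = 0.264), with 877 at an unadjusted p under 0.05 and 709 given by chance. The smallest p-values, not past the threshold, were for Lysmd4 (0.53 ± 0.12), the chromatin assembly gene Chaf1a (0.59 ± 0.14), Sap130 (0.46 ± 0.12), Plekhm1 (0.31 ± 0.08) and Exd1 (0.67 ± 0.18) on the side higher on the high-fat diet. On the other side were Nmrk2 (-9.55 ± 1.65), Nr4a1 (-2.84 ± 0.59), Mylk4 (-11.41 ± 2.45), Scn4a (-8.35 ± 1.82) and Rpl3l (-8.04 ± 1.77), most of which are muscle genes. An antibody effect seen on 1 diet alone is therefore not shown to differ between diets for any single gene. For the genes named in every comparison the interaction had adjusted p from 0.87 (Pdgfra and Pparg) to 0.94 (Adipoq), with Pdgfc at 0.931, Fasn at 0.875 and Ucp1 at 0.89. By camera with the preset correlation 13 lists differed between the diets, and none did with an estimated correlation, where adjusted p lay between 0.718 and 0.895. The antibody effect was more positive on the high-fat diet for cholesterol biosynthesis (median difference 0.48; adjusted p = 0.000413, adjusted p = 0.88 with an estimated correlation), de novo lipogenesis (0.42, 0.00066) and fatty acid oxidation (0.42, 0.00298). So it was for lipolysis (0.28, 0.00596), oxidative phosphorylation (0.23, 0.00711) and mature adipocyte genes (0.14, 0.0491). It was more negative for skeletal muscle (-9.08; adjusted p = 3.62e-16, adjusted p = 0.718 with an estimated correlation), immediate early and stress (-0.80, 8.35e-08) and macrophage genes (-0.39, 7.89e-05). So it was for Schwann cell and nerve (-0.55, 0.00105), adipose progenitor (-0.25, 0.00348), inflammatory cytokines and chemokines (-0.33, 0.0143) and circadian clock genes (-0.34, 0.0162). Members past the threshold adjusted over the list alone were 11 for skeletal muscle, 3 for immediate early and stress, 1 for adipose progenitor and 0 for the others.

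Single libraries ended several of these list calls. The mature adipocyte difference lost its call without untreated control-diet replicates 2 and 3 (adjusted p = 0.122 and 0.187), antibody control-diet replicates 1 to 3 (0.0994, 0.0798 and 0.0655). It also lost it without untreated high-fat replicates 2 to 4 (0.177, 0.108 and 0.0508) and antibody high-fat replicates 1, 2 and 4 (0.051, 0.0912 and 0.0526). Oxidative phosphorylation lost it without untreated control-diet replicates 3 and 4 (0.411 and 0.138), antibody control-diet replicate 4 (0.101), untreated high-fat replicate 2 (0.0605) and antibody high-fat replicate 1 (0.0859). Inflammatory cytokines lost it without untreated control-diet replicate 3 (0.162), untreated high-fat replicates 3 and 4 (0.0726 and 0.0538) and antibody high-fat replicate 4 (0.0548). Without untreated control-diet replicate 3 the calls of lipolysis (0.0743), fatty acid oxidation (0.215) and adipose progenitor (0.0743) ended, and without untreated high-fat replicate 2 that of lipolysis (0.0525). Circadian clock lost its call without untreated control-diet replicates 1 and 2 and untreated high-fat replicate 1 (0.181, 0.0725 and 0.13). Without both doubted libraries the calls of mature adipocyte (0.548), lipolysis (0.343), fatty acid oxidation (0.614), oxidative phosphorylation (0.834) and inflammatory genes (0.0628) ended. With quantile normalization those of mature adipocyte (0.777), lipolysis (0.105) and oxidative phosphorylation (0.108) ended, and that of mature adipocyte also after centring (0.0675) and with the stricter filter (0.0571). With the muscle score as a covariate no call remained for mature adipocyte (0.242), de novo lipogenesis (0.976), lipolysis (0.536), fatty acid oxidation (0.875), oxidative phosphorylation (0.111), cholesterol biosynthesis (0.883), adipose progenitor (0.297), macrophage (0.104) or Schwann cell genes (0.105), and the mean differences of oxidative phosphorylation (-0.19) and cholesterol biosynthesis (-0.0486) turned negative.

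**Figure D5:**
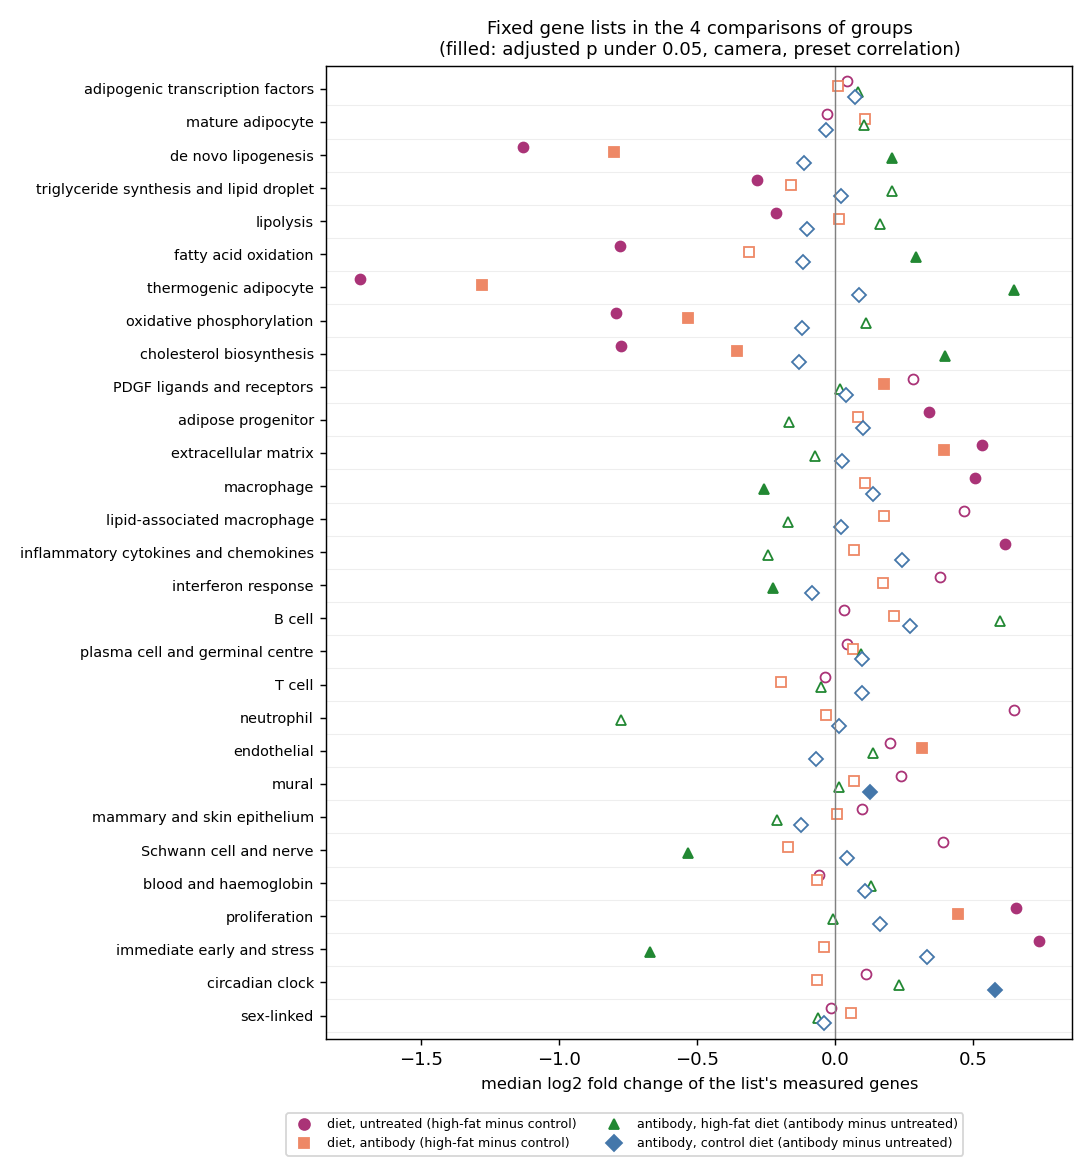
Median log2 fold change of the members of 29 gene lists (rows) in 4 comparisons (colours), with filled points where camera with the preset correlation gave an adjusted p under 0.05; skeletal muscle is left out for scale. De novo lipogenesis lies at -1.13 for the diet without antibody, at -0.80 for the diet with antibody and at 0.21 for the antibody on the high-fat diet.

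Across all 14189 genes the antibody effects on the 2 diets, which share no library, had Pearson r = -0.502 and Spearman rho = 0.198, with the same sign in 57.2% of genes. With the muscle score in the model r was 0.116, so its sign turned, and with the clock score it was -0.154. The calls on the 2 diets shared Bahcc1 alone, with 0.00282 shared rises given by independent lists. The diet effects without and with antibody, which also share no library, had r = -0.0159 and rho = 0.533, and the same sign in 72.5% of genes. Orm3 was the only gene called in both (0.0517 shared falls given by independent lists). The diet effect without antibody and the antibody effect on the high-fat diet had r = -0.549, rho = -0.409 and the same sign in 37.1% of genes, but both use the untreated high-fat libraries. Unchanged groups with a shared group were simulated from within-group deviations drawn at random over the libraries of all groups. They gave a mean r of -0.509 (-0.87 to 0.211 in 100 draws) and 32.6% with the same sign. The simulated shared group was thus a random mix and does not hold the spread of the untreated high-fat libraries in particular. The observed covariance was -0.115 against a simulated -0.0377 (-0.129 to 0.0111), a difference of -0.0777. With the untreated high-fat libraries split into sets of 2 the mean r over 6 splits was -0.328 (-0.509 to -0.215). Genes are not independent replicates, so no p-value is given for these correlations.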

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

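Chosen only after the results were seen were the muscle-RNA and antibody tests of the clock genes, the tests of the muscle genes, and the adipocyte-share and library-exchange tests of the lipogenic genes, and the comparison of lists between the sides of a split; the time-of-day and thermogenic tests and all splits were written before.

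Clock genes as a list shifted with the antibody on the control diet, and most of them had the same sign on the high-fat diet. On the control diet the fixed list of 15 clock genes passed with the preset correlation (median 0.579, adjusted p = 0.718 with an estimated correlation), and on the high-fat diet it did not (median 0.23, adjusted p = 0.15), with 1 and 0 of its genes past the threshold. Skeletal muscle RNA was excluded as the source, since 13 of 15 clock genes had the same sign on both diets (Dbp 1.32 and 1.09, Arntl -1.16 and -1.36) while muscle genes had opposite signs; the exceptions were Per1 (0.23 and -0.622) and Nr1d1 (-0.0391 and 0.155). Collection at another time of day and an antibody effect on the clock or on feeding cannot be told apart here: of 4 other rhythmic genes on 2 diets, 8 of 8 signs went the way predicted from the clock genes (Usp2 1.44 and 0.276, Nfil3 -0.495 and -0.599), and the larger exact permutation p of the list mean over the 2 diets was 0.114. The list mean joins genes that rise with genes that fall, so it can miss a shift of phase. The clock score differed by 1.98 and 1.66 on the control and high-fat diets (exact permutation p = 0.0286 each). It varied widely within the untreated groups, from 0.1532 to 2.573 on the control diet (SD 1.17) and from 0.6931 to 2.205 on the high-fat diet (SD 0.646). The span within the untreated control-diet libraries was thus larger than the antibody difference there. In antibody libraries the SD was 0.45 and 0.428. The genes of the clock score were chosen after the data were seen, so its exact permutation p is not an independent test. What stays open is the time of day at which each library was collected, which is not given in the sources used here.

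Skeletal muscle genes were higher with the antibody on the control diet (score 8.431 ± 3.29 to 11.72 ± 0.513, exact p = 0.0286, difference 3.29, or 1.71 without untreated control-diet replicate 4) and lower with it on the high-fat diet (10.16 ± 2.24 to 5.299 ± 2.33, exact p = 0.0571). Muscle tissue collected with the fat pad is a candidate explanation that was not excluded: 16 of 16 other muscle genes went the same 2 ways (Ttn 4.8 and -6.56), 0 of the 14 muscle genes are on another list, and Acta1 reached 92644 normalized counts in untreated high-fat replicate 2 and was 102.9 in antibody high-fat replicate 1. The opposite directions stand against an antibody effect on muscle that is the same on both diets, though the larger exact permutation p of 0.0571 limits this. An antibody effect that differs between the diets cannot be told apart from muscle collected with the fat pad. What stays open is whether any muscle was in the dissected tissue.

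Lipogenic genes were lower on the high-fat diet without antibody (median -1.13). A smaller share of adipocytes was excluded, as the 23 mature adipocyte genes off the lipogenic list had a median of -0.00795. Its bootstrap SE of 0.0784 is over genes and holds no spread between libraries. Between libraries the mean of the full mature adipocyte list, as a deviation from all libraries, was -0.0486 ± 0.0887 on the control diet. On the high-fat diet it was -0.034 ± 0.147 (SD, n = 4). The thermogenic state of single control libraries was excluded as the whole source of the fall, as the median with that score as a covariate was -0.911. A contribution was not excluded, since the rule asked only that the median stay beyond -0.564, and no SE was computed for it. An exchange of the untreated replicate-1 libraries between diets was excluded as the source of the fall. With these exchanged the median was -1.3 (bootstrap SE over genes 0.342). Whether these labels are right stays open, as do, untested, the composition and length of the diets: between control-diet and high-fat replicate 1 Ucp1 ran against the labels (206.78 and 6052.9 normalized counts), Fasn (278930 and 196660) and Acly (25480 and 15694) ran with them, and from the midpoint of the lipogenic score they lay at -0.171 and -0.42, both on the high-fat side.

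For the count of genes between diets without antibody, chance in the grouping of libraries cannot be excluded: 2 of 35 splits of the 8 libraries gave at least as many genes, with 1157 for the real split and 3733 for the highest other, in which untreated replicate 1 of each diet was exchanged. A split with so many more genes points to a structure of the samples, and its sides differed in thermogenic level: the mean log2 value of the thermogenic list was 6.593 to 7.355 on the side of control-diet replicate 1 and 9.304 to 11.39 on the other. In all, 13 of 30 lists parted the sides without overlap, among them fatty acid oxidation (11.36 to 11.54 and 12.29 to 13.3) and macrophage genes (11.03 to 11.52 and 10.16 to 10.59), and the cause was not tested. This split was picked for its count of genes, so lists that part its sides follow in part from that choice. De novo lipogenesis did not part its sides (12.58 to 13.5 and 13.25 to 14.77). That list did part the real split, with means as deviations from all libraries of -0.1192 to 1.154 on the control diet and -1.039 to -0.3685 on the high-fat diet. The thermogenic list did not part the real split (-1.649 to 2.592 and -2.202 to 0.7246). Lists were not counted in this way for the real split.

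By a test for 1 library far from the other 3 of its group, with a chance of about 1 in 20 per test, 24 of 372 values stood apart. That share is not far above 1 in 20, so many of these values can stand apart by chance. Among untreated control-diet libraries these were Lep at log2 12.79 in replicate 2 (others 13.86 to 13.99), Nmrk2 at 2.729 (0 to 0.2079) and Nr4a1 at 7.38 (6.792 to 6.858) in the same library, and the immediate early and stress list at 7.706 in replicate 4 (7.553 to 7.574). Among antibody control-diet libraries Mt2 was 8.773 (9.699 to 9.807) and the circadian clock list 10.24 (10.31 to 10.32) in replicate 1, and the Schwann cell and nerve list 8.387 (9.008 to 9.098) in replicate 2. Replicate 3 of that group had Pparg at 12.37 (12.95 to 13.04), Mylk4 at 8.84 (11.31 to 11.65), Rpl3l at 6.224 (8.077 to 8.216) and a library total of 24.56 in units of 1e6 (25.61 to 25.74). Replicate 4 had Zbtb16 at 10.08 (9.741 to 9.762), Xrcc3 at 6.633 (7.157 to 7.181) and the mature adipocyte list at 15.39 (15.25 to 15.26). In untreated high-fat replicate 1 Cxadr was 6.799 (4.616 to 4.826), Pdgfc 9.26 (9.507 to 9.546), Exd1 8.21 (7.771 to 7.842) and the triglyceride synthesis and lipid droplet list 12.65 (12.04 to 12.13), and in replicate 4 the T cell list was 5.209 (5.433 to 5.469). In antibody high-fat replicate 2 Nmrk2 was 2.792 (0 to 0) and the immediate early and stress list 7.537 (7.797 to 7.845). In antibody high-fat replicate 3 Cxadr was 4.519 (6.875 to 7.236), the triglyceride synthesis and lipid droplet list 12.09 (12.38 to 12.42) and the lipolysis list 13.34 (13.56 to 13.6).

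The antibody effect differed between the diets for 13 of 30 lists at an adjusted p under 0.05 with the preset correlation, and for 0 with an estimated correlation (adjusted p = 0.718 to 0.895). The median difference, high-fat minus control diet, was 0.135 for mature adipocyte, 0.416 for de novo lipogenesis, 0.278 for lipolysis, 0.423 for fatty acid oxidation, 0.227 for oxidative phosphorylation and 0.485 for cholesterol biosynthesis. It was -0.252 for adipose progenitor, -0.387 for macrophage, -0.328 for inflammatory cytokines and chemokines, -9.08 for skeletal muscle, -0.554 for Schwann cell and nerve, -0.802 for immediate early and stress and -0.337 for circadian clock genes.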

How the results depend on the processing

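Leaving out both doubted libraries and the muscle and clock scores as covariates were chosen after the results were seen; the other settings were written before. With each library left out, the count of genes past the threshold ranged from 0 (without untreated control-diet replicate 4) to 4119 (without replicate 1) for the diet without antibody, against 1157. It ranged from 1 (without untreated control-diet replicate 2) to 271 (without untreated high-fat replicate 1) for the antibody on the high-fat diet, against 11, and from 0 (without antibody control-diet replicate 3) to 86 (without untreated high-fat replicate 2) for the antibody on the control diet, against 14. For the diet with antibody it ranged from 0 (without antibody control-diet replicate 1) to 239 (without untreated high-fat replicate 2), against 1, and for the interaction from 0 to 1 (without untreated high-fat replicate 1). The correlation of the antibody effects between diets ranged from -0.562 (without untreated control-diet replicate 1) to -0.308 (without replicate 4), and that of the diet effect and the antibody effect on the high-fat diet from -0.686 (without untreated high-fat replicate 1) to -0.381 (without untreated control-diet replicate 4). Weights per library gave 4380 genes for the diet without antibody, 1330 and 757 for the antibody on the high-fat and control diets and 1099 for the diet with antibody, with weights from 0.28 (untreated control-diet replicate 3) to 3.77 (replicate 2). Without a variance trend there were 726 genes for the diet without antibody and 3 for the antibody on the control diet, and with no filter 2 for the diet with antibody. Centring gave 7 for the antibody on the control diet, 5 higher and 2 lower, and split the calls on the high-fat diet into 10 higher and 6 lower; quantile normalization split them into 11 and 4 there and 9 and 10 on the control diet. A log2 fold change of at least 1 was met by 172, 7 and 5 genes for the diet without antibody and the antibody on the high-fat and control diets. The replicate number as a block gave 0 genes for the diet without antibody, 2 and 2 for the antibody on the high-fat and control diets, 0 for the diet with antibody and 1 for the interaction, and as a block within diet 0 and 4 for the antibody on the high-fat and control diets. The block within diet ended the mural call on the control diet (adjusted p = 0.0518) and the block the mature adipocyte call of the interaction (0.0606), but the pairing check found r over 0.1 in 10 of 24 pairs of the same number, and 6 of 16 libraries closest to their own number, with all 6 pairs of replicate 2 over 0.1 (0.126 to 0.487) and at most 2 of 6 for each other number, so the numbers are not shown to pair libraries as a whole. With only the groups compared the counts were 0 for the diet without antibody, 4 and 0 for the antibody on the high-fat and control diets and 641 for the diet with antibody, and without both doubted libraries 0 for the diet without antibody and 298 for the diet with antibody. With the muscle score as a covariate 119 genes passed for the diet without antibody and 0 and 5 for the antibody on the high-fat and control diets; the correlation of the antibody effects turned to 0.116 and that of the diet and antibody effects was -0.204. In that fit the list means of thermogenic genes for the antibody on the high-fat diet (-0.223) and of oxidative phosphorylation (-0.19) and cholesterol biosynthesis (-0.0486) for the interaction turned negative. With the clock score as a covariate 2609 genes passed for the diet without antibody and 2 and 0 for the antibody on the high-fat and control diets, and the correlations were -0.154 and -0.0901. Its list means for the antibody on the high-fat diet turned sign for de novo lipogenesis (-0.232), fatty acid oxidation (-0.391), thermogenic adipocyte (-0.795), macrophage (0.225) and interferon response (0.0337). The muscle list has no value with the muscle score, which is fixed to 0 by construction; the cause of the other changes was not tested. Of the remaining list results 1041 were the same and 147 weaker. With an estimated correlation all 47 list calls were weaker, so none passed there. Of the results of named genes 2358 were the same, 508 weaker, 21 stronger and 53 moved. Alternatives that model whole reads were not run, since whole reads could not be recovered.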

Other observations

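The antibody effect averaged over both diets, the test of glucocorticoid-responsive genes and the comparison of lists between the sides of a split were chosen after the results were seen; the permutations of the averaged effect and the test of the genes that move with Ucp1 were written before their own outcomes were seen.

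Averaged over both diets, 358 genes passed the threshold with the antibody by limma, 218 higher and 140 lower, 39 of them at least 2-fold. Zbtb16 fell by 1.77 ± 0.19 (adjusted p = 0.000764) and Cdkn1a by 1.39 ± 0.18 (0.00247), with 8 and 7 of 8 antibody libraries below all untreated ones, and Bahcc1 rose by 1.06 ± 0.11 (0.000647). Smim10l2a (1.42 ± 0.23, adjusted p = 0.00655), Rasl12 (1.31 ± 0.18, 0.00354) and the protease gene Adamts6 (1.24 ± 0.18, 0.00444) rose with all 8 antibody libraries beyond all untreated ones. Foxo6 (2.04 ± 0.44, 0.0267), Rcor2 (1.34 ± 0.29, 0.0251) and the clock output gene Hlf (1.33 ± 0.26, 0.016) rose as well. The chemokine gene Cxcl14 (-1.10 ± 0.20, adjusted p = 0.0129), the clock genes Arntl (-1.26 ± 0.28, 0.0309) and Npas2 (-1.17 ± 0.26, 0.0306) and Alkal2 (-1.28 ± 0.26, 0.0216) fell. Of 15 circadian clock genes 9 passed, and the clock list was the only one called (median 0.342, adjusted p = 0.00549, adjusted p = 0.961 with an estimated correlation). Of 18 adipogenic transcription factors 3 passed: Zfp467, which favours adipogenesis, rose by 0.82, the lipogenic regulator Srebf1 rose by 0.80 and Klf15 fell by 0.55. The cholesterol genes Fdft1 and Stard4 rose by 0.76 and 0.56, and the mural genes Kcnj8 and Cspg4 by 0.71 and 0.64. The count was 144 without untreated control-diet replicate 2, 209, 187, 210 and 151 without antibody control-diet replicates 1 to 4, 155 and 154 without untreated high-fat replicates 3 and 4, and 160 and 234 without antibody high-fat replicates 2 and 4. Weights per library gave 1958 genes. The replicate number as a block gave 123 and as a block within diet 52, where the pairing check found r over 0.1 in 10 of 24 pairs of the same number. The muscle score gave 304 and the clock score 3, so most of the 358 calls were not kept once the clock score was in the model. The clock score was itself chosen after the clock genes were seen, and it was higher with the antibody by 1.98 and 1.66 on the control and high-fat diets, so that model also removes part of any antibody effect. Of 100 permutations of the antibody labels within diet only the real one reached 358 genes, and the highest other gave 1. Chance in the grouping of libraries is an unlikely source of that count, though the averaged effect was chosen after the results were seen.

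A lower glucocorticoid signal was tested as a source of the lower Zbtb16 and Cdkn1a with the antibody on the high-fat diet, since both are known glucocorticoid targets. The mean of 14 other glucocorticoid-responsive genes was 9.778 ± 0.0975 with the antibody against 10.57 ± 0.429 without (difference -0.789, n = 4, exact permutation p = 0.0286, the smallest possible), so this explanation was not excluded. Fkbp5 was at -1.23, Tsc22d3 at -0.905, Errfi1 at -1.44, Mt2 at -2.09 and Cebpd at -0.963, and Ddit4 at 0.536 was the exception. On the control diet the difference was 0.099 (exact permutation p = 0.657), while Zbtb16 was at -1.30 ± 0.27 and Cdkn1a at -1.23 ± 0.25 there, not past the threshold (adjusted p = 0.0771 each). That difference was 0.159, -0.0236, 0.205 and 0.0554 without untreated control-diet replicates 1 to 4, and 0.248 and -0.00701 without antibody control-diet replicates 1 and 4. The mean of the 14 genes was 9.956 ± 0.309 in untreated and 10.05 ± 0.322 in antibody control-diet libraries, so untreated high-fat libraries were the highest group. Without antibody it was higher on the high-fat diet by 0.611 (exact permutation p = 0.0857). A rise in untreated high-fat libraries and a fall with the antibody cannot be told apart here. The genes were chosen after the data were seen, so the p of 0.0286 is not an independent test. Corticosterone levels and handling stress, which could separate the readings, are not given in the sources used here.

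Ucp1 differed widely between libraries of 1 group, from 206.78 to 44771 normalized counts in untreated control-diet libraries. After group means were removed, the other 17 thermogenic genes had a median Pearson r of 0.928 with Ucp1 over 16 libraries (0.893 without the 2 farthest libraries), so a shared thermogenic programme was not excluded. Cidea had the highest r (0.982) and Prdm16 the lowest (0.377). Of the 17 relations 16 had a permutation p under 0.05 after adjustment by r and by rho, and Prdm16 had 0.238. The mean of the 17 genes had r = 0.975 and rho = 0.988 (permutation p = 1e-05 for each, the smallest possible with 100000 draws) and r = 0.972 without the 2 farthest libraries.

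For the antibody on the high-fat diet only the real split, 1 of 35, gave 11 genes, and the highest other gave 6. That is the smallest share that 35 splits allow, and other comparisons were split as well. Chance in the grouping of libraries is therefore made less likely here but is not excluded. For the antibody on the control diet it cannot be excluded: 2 of 35 splits gave at least the real 14 genes, and the highest other gave 245, with untreated replicates 1 and 2 and antibody replicates 3 and 4 on one side, which points to a structure of the samples. Its sides were parted without overlap by 7 of 30 lists, among them thermogenic (7.146 to 9.39 and 9.844 to 11.39) and de novo lipogenesis genes (13.5 to 14.07 and 14.39 to 14.77), and the cause was not tested. This split too was picked for its count of genes, so lists that part its sides follow in part from that choice. For the diet with antibody 2 of 35 splits gave at least the real 1 gene (highest other 1), so chance cannot be excluded. For the interaction the real count was 0, which 100 of 100 permutations must reach (highest other 0), so this says nothing on chance.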
